A study of Mus musculus with 17 samples.

How the data were processed

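Gene expression was measured by RNA sequencing in 17 frozen samples of prostate tissue or prostate tumour from C57BL/6 mice, among them wild type (n = 3), Ctnnb1 with exon 3 deleted (n = 3), that allele with a further engineered change (n = 3), and an inducible model of the last genotype with mock treatment (n = 2) or androgen deprivation (n = 3). A further genotype group (n = 3) that was part of the fit, the comparisons that rest on it or on the further engineered change alone, and some of the genes that the rules below take are not reported here. Per the labels' protocols, RNA of integrity above 7.3 was sequenced by BGI on a HiSeq 2000 as paired reads of 90 nt, with at least 6 Gb per sample. Per the submitters' processing notes, the authors used FastQC 0.11.4, TopHat2 2.1.0, Bowtie2 2.2.6.0, HTSeq 0.6.0, R 3.2.3 and DESeq2 1.14.1 with the build GRCm38.p3; the notes do not state the role or settings of each tool.

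The deposited values are scores on a scaled count basis: the authors divided gene counts by a size factor per library and rounded the result, as judged from the values, whose median ratios within each set of files lie between 0.981 and 1.01. The raw counts and the size factors were not used here, so the sequencing depth per gene and the precision that depth gives cannot be stated. The design had assumed counts and named a test for scaled values in case they were not, and that test was used.

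The files came in 3 sets. Those of the wild-type and Ctnnb1 groups list 15195 features by Entrez number, those of the further genotype group 15617 by Ensembl identifier, and those of the inducible model 42847. Features without an Entrez number (631 and 738 in the first sets), Entrez numbers given to more than 1 feature (118 and 120) and features that repeat a gene's values under another number (386, 381 and 3668) were left out, which kept 13908, 14228 and 39179 genes. In the inducible model, 15208 missing symbols were filled from a table of gene names. Counts of reads outside genes, 7.02% to 8.13% of the totals, were removed from the second set. The genotype table holds the 13683 genes found in both of its file sets, and 225 and 545 genes listed in only a single set were left out of the comparisons. The lowest mean of a gene over the 9 libraries of the first set was 15.6, so genes of low value had been removed from it, and a gene missing from a table is not a gene without expression. For 4 list members the symbol in the files differs (Emr1 for Adgre1, Il8 for Cxcl15, Hbb-b2 for Hbb-bt and Igj for Jchain). Gene positions came from GENCODE M21.

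Values were taken as log2(value + 1). A gene was tested when at least 3 of the 12 genotype libraries, or 2 of the 5 libraries of the inducible model, had a value of at least 1. The 12 genotype libraries were fitted together with group as the only factor, and contrasts of groups were taken from that fit. The 5 libraries of the inducible model were fitted alone. The tests were the moderated tests of limma 3.58.1 with a trend in the prior variance, in R 4.3.3, adjusted by Benjamini-Hochberg over the genes of a comparison. A gene is called changed at an adjusted p under 0.05, and SE is the moderated standard error. Tables and figures were made in Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9. No factor for age was fitted, because age and group differ together.

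The genes named were set by a rule written before the values were seen. It takes Ctnnb1 in every comparison, and adds the 8 highest and 8 lowest log2 changes among called genes with a mean value of at least 5, no overlap between the groups, and a symbol that is not a clone or model name or an antigen receptor segment. Up to 4 members with the smallest p were taken from each fixed list, along with members shown as values. The text names part of these, and prefers those whose call stood without any library. The exceptions, chosen after their values were seen, are 9530053A07Rik and, in the closing part, Alb, Afp, Ahsg, Xist, the Y-linked genes, Foxa2 and Hsd17b3.

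Before the values were seen, 29 gene lists were fixed. They cover Wnt target genes, androgen-regulated and secretory luminal genes, steroid synthesis and conversion genes, FOXO target genes, cell cycle genes, p53 and senescence genes, and luminal, luminal progenitor-type, basal, squamous, neuroendocrine and urothelial epithelial markers. Others hold markers of macrophages, neutrophils, T and NK cells, B and plasma cells, smooth muscle, skeletal muscle, fibroblasts, endothelium, adipocytes, red blood cells and seminal vesicle. The last hold cytokine, interferon response, hypoxia, cholesterol, unfolded protein response and immediate-early genes. Lists with at least 3 tested members were tested with camera of limma at a preset correlation of 0.01 and with an estimated correlation, adjusted over the lists of a comparison. Calls of members were also counted after adjusting over the list alone.

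The overlap between comparisons with wild type was set beside the product of the list sizes divided by the number of genes, and beside 20 simulations of unchanged groups against the same controls. The test was also tested on simulated data with 100 genes changed by 1 and 100 by 2 on the log2 scale. In data simulated for the comparison of Ctnnb1 tumours with wild type it recovered 54 and 81 of these and called 6 unchanged genes, and in data simulated for the androgen deprivation comparison it recovered 0 and 0.

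Alternatives tried were other pseudocounts (0.1 and 5), no filter, a stricter filter (1 per 1e+06 of the total), a fit of only the groups compared, a fit of all 17 libraries, a replicate block, the omission of each library, fry in place of camera, and a fold threshold for the overlap. Rescaling of the scores by median ratio, upper quartile or total, a robust prior variance, a fit of the 9 libraries from a single file set, and a fit of the inducible model with only the genes of the 17-library fit were added after the data were seen. Alternatives that need raw counts were not run.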

Results

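RNA sequencing measured transcript levels in mouse prostate tissue and prostate tumours. Wild-type prostate, tumours with a Ctnnb1 allele lacking exon 3 (the Ctnnb1 group) and tumours with that allele and a further engineered change (the combined group) had 3 libraries each. Exon 3 encodes the part of beta-catenin through which the protein is marked for breakdown, so its loss leaves a stable protein that drives Wnt target genes. An inducible model of the combined genotype gave 2 mock-treated and 3 androgen-deprived (ADT) libraries. The mice were 12 months old in the wild-type and Ctnnb1 groups, 6 to 8 in the combined group and 15 in the mock and ADT groups. Age and genotype therefore differ together in the combined group. The labels give the number of samples per group and do not say that each came from a separate animal.

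The values were gene read counts that the authors had divided by a size factor per library and rounded, so their totals are not sequencing depths. Totals over all listed features were 46916133, 45675083 and 47248750 in the wild-type libraries. They were 35120175, 34918494 and 33903149 in the Ctnnb1 group and 32455483, 34376245 and 33942222 in the combined group. The mock libraries held 32054108 and 30591734 and the ADT libraries 32335993, 31583684 and 32791101. Over the genes kept, the wild-type totals were 38313542, 37222401 and 38995571. A secretory transcript, 9530053A07Rik, took 13.3%, 15.0% and 10.9% of these smaller totals, and the 10 highest genes took 25.1%, 24.9% and 28.2% of them. The mock and ADT values came from a separate set of files and were compared only with each other. Every fold below is on the scale of log2(value + 1), and every test of single genes is limma's moderated test with Benjamini-Hochberg adjustment. A named gene that is called kept its call when any of the compared libraries was left out, unless stated.

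Ctnnb1 (Entrez 12387; GRCm38 chromosome 9, 120929216 to 120960507, with exon 3 at 120950522 to 120950749) was at 18785, 18850 and 18320 in wild-type, 25993, 26125 and 26930 in Ctnnb1 and 27677, 29542 and 32871 in combined libraries. It was at 30608 and 40205 with mock treatment and 64204, 76649 and 74725 under ADT. The total covers exons outside the deleted part, so it checks nothing about the deletion, and each library keeps its label as given.

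**Figure D1:**
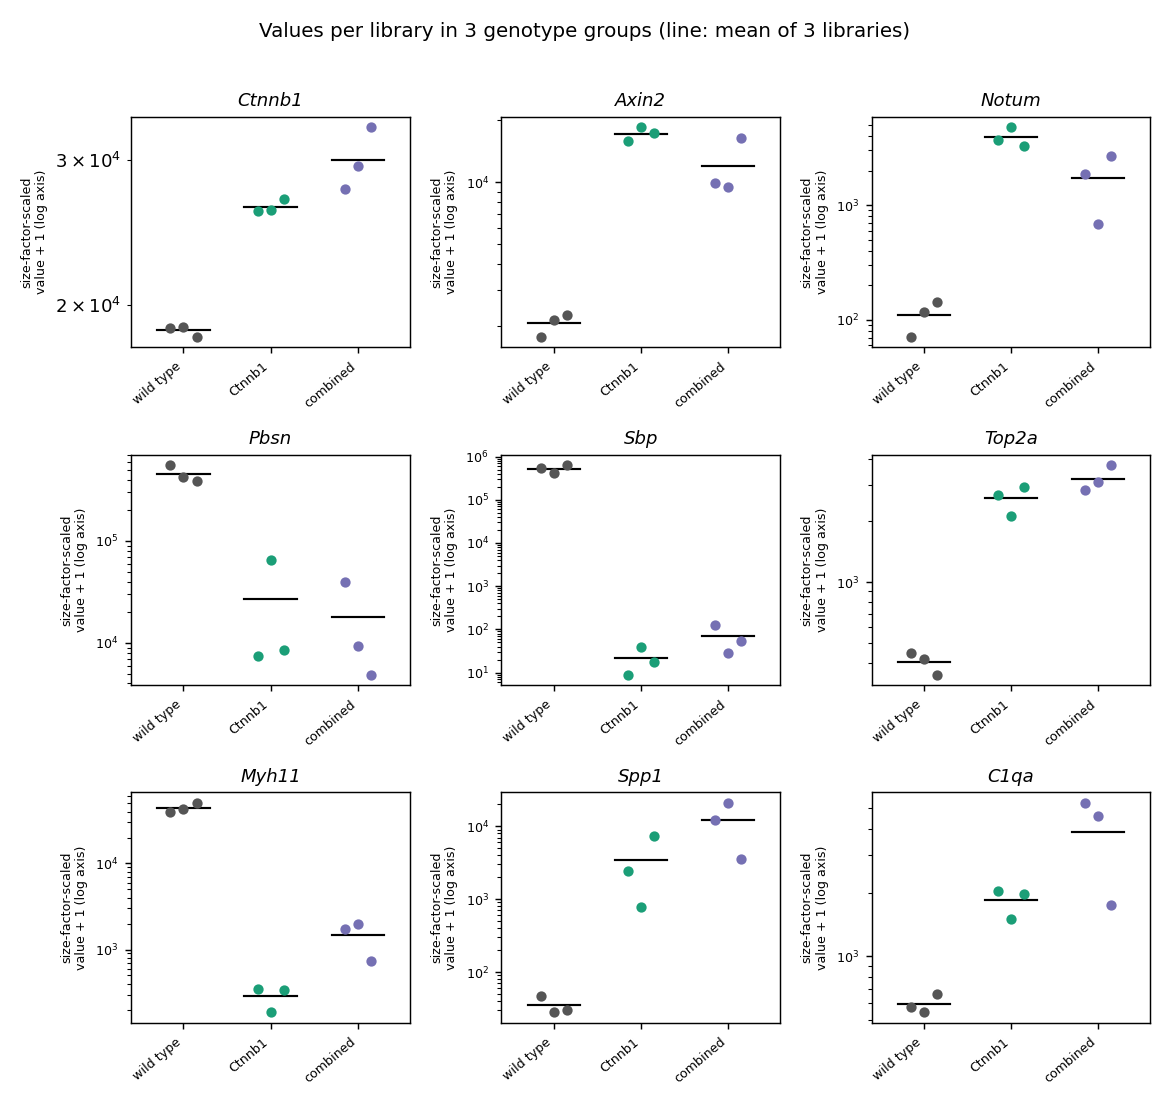
Size-factor-scaled value plus 1 (log axis) of 9 genes in each library of the wild-type, Ctnnb1 and combined groups; points are libraries and lines are means of 3. Axin2, Notum and Top2a lie above wild type in both groups with the Ctnnb1 allele, and Pbsn, Sbp and Myh11 lie below it.

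The Ctnnb1 group, without the further engineered change, was compared with wild-type prostate. Tumour and prostate pieces can also differ in the tissues they hold, so the contrast does not isolate the effect of a stable beta-catenin. limma called 7784 of 13683 genes, 3777 higher and 4007 lower, with 3555 at least 2-fold. The groups did not overlap for 9761 genes, where chance gives 10% of genes for 3 against 3. Axin2, a feedback gene of the Wnt pathway, averaged 17170 ± 1314 against 2064 ± 258 (n = 3 each; log2 change 3.06, SE 0.27, adjusted p 2.01e-05 in limma). Of 28 fixed gene lists with at least 3 tested members, limma's camera with its preset correlation called 6 as higher and 6 as lower. With an estimated correlation it called 0 lists in this and in each of the 2 other comparisons. The camera values given are those with the preset of 0.01, which was the planned test. Estimated correlations in this comparison ran from 0.125 (FOXO target genes) to 0.897 (skeletal muscle markers). For the cell cycle genes the estimate was 0.787, with a camera adjusted p of 0.701. Where members vary together this far, p values with the preset can be far too small. At an unadjusted p under 0.05 the estimated correlation gave 3, 0 and 3 lists, in the order of the comparisons. Notum (log2 change 5.20, SE 0.53, adjusted p 3.95e-05 in limma) and Apcdd1 (log2 change 5.21, SE 0.51, adjusted p 3.36e-05 in limma) were higher as well. Of the 17 tested Wnt target genes 15 rose and 2 were not called (median 2.05, camera adjusted p 2.08e-06). Ctnnb1 itself was higher (log2 change 0.50, SE 0.09, adjusted p 0.00127 in limma).

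Of the genes in the genotype table that the naming rule admits, those that rose most included Tgm3 (7.64), Prr9 (7.62), Krt16 (7.53), Samd5 (7.39), Vil1 (7.33), Krt6a (7.08) and Coch (6.65), and Coch averaged 45960 ± 30300 against 399 ± 20.6 (n = 3 each). Genes listed outside that table were not ranked. Genes of secretory fluid were among those that fell most, with Spink3 (-16.29), Svs1 (-14.81), Sbp (-14.78), Spinkl (-13.61), Svs6 (-11.92) and Svs5 (-11.59), and the secretoglobin genes Scgb2b7 and Scgb2b20 were listed at 0 in all 3 Ctnnb1 libraries. Sbp averaged 21.0 ± 15.4 against 528500 ± 109700 (n = 3 each; SE 1.36). Androgen-regulated and secretory luminal genes had 10 of 15 members lower and 1 higher (camera 0.0106; Slc45a3 (-2.42) and Abcc4 (-2.37)). All 8 seminal vesicle markers fell (camera 0.00904; Svs2 (-10.61)), as did 8 of 9 skeletal muscle markers (0.0261; Acta1 (-8.57)). The wild-type libraries stand far apart for these seminal genes (Svs1 at 9346, 16374 and 466665, Svs2 at 801907, 146860 and 1826136 and Svs5 at 247409, 154592 and 1140841), so the sizes of these falls depend on the wild-type pieces, and what those pieces held was not tested for the seminal vesicle. Camera did not call the muscle list without wild-type replicate 1 or Ctnnb1 replicate 13 or 14. All 10 smooth muscle markers were lower (median -5.77, camera 9.15e-07), among them Myh11 (log2 change -7.30, SE 0.50, adjusted p 6.77e-06 in limma) and Cnn1 (-8.22). All 7 tested of the 11 neuroendocrine markers fell (camera 0.00316; Scg2 (-5.10) and Syp (-3.95)), and 10 of 11 unfolded protein response genes did (0.00252; Sdf2l1 (-1.75) and Creld2 (-2.20)). Foxa2, a neuroendocrine marker outside the genotype table, was higher in a separate fit given in the closing part.

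All 23 cell cycle genes rose in the Ctnnb1 group (median 2.67, camera 8.83e-11), including Mki67 (3.42) and Top2a (2.66). Squamous keratinisation markers rose for 6 of 10 members (camera 0.0106; Krt6a (7.08) and Krt16 (7.53)) and macrophage and monocyte markers for 10 of 12 (0.00904; Arg1 (2.35) and C1qa (1.62)). Cytokine and acute-phase genes rose for 9 of 12 (0.00145; Il1b (3.66) and Spp1 (6.14)). Interferon response genes had 12 of 15 members higher and 1 lower (camera 0.00131; Oas1a (2.53) and Ifi44 (2.50)). Of 11 p53 and senescence genes 7 rose and 2 fell (Cdkn2a (6.55) and Sesn2 (-1.41)), and camera called the list only without Ctnnb1 replicate 15. Neutrophil markers had 3 of 6 and T and NK cell markers 4 of 7 members higher (Csf3r (2.25) and Cd8a (3.03)). B and plasma cell markers had 0 of 7 called, and fibroblast and matrix genes had 1 of 10 lower, and camera called none of these 4 lists. Luminal progenitor-type markers divided into 3 higher and 2 lower (Ppp1r1b (-1.03) among the lower), with a median of -0.25 but a mean of 0.34 and camera pointing up (0.785). For FOXO target genes 4 of 16 were higher and 2 lower (Erbb3 (1.12) and Cited2 (-2.39)), with a median of -0.02 and camera pointing up (0.977). Cholesterol and fatty acid synthesis genes also differed in sign between median (0.05) and mean (-0.07), with 4 of 15 higher and 3 lower (Elovl6 (1.87) and Insig1 (-1.39)). Adjusted over the list alone, calls came to 15 of 17 for the Wnt target genes, 11 of 15 for the androgen-regulated and secretory luminal genes, 10 of 11 for the p53 and senescence genes, 11 of 12 for the cytokine and acute-phase genes and 6 of 16 for the FOXO target genes.

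The combined group was compared with wild-type prostate in the same fit, in mice of different ages. limma called 7711 of 13683 genes, 3693 higher and 4018 lower, 3623 of them at least 2-fold. By camera 9 lists were higher and 4 lower, and 9046 genes did not overlap between the groups (10% by chance). Ctnnb1 was higher (log2 change 0.68, SE 0.09, adjusted p 1.94e-04 in limma). Spp1, the osteopontin gene, was among the genes admitted by the naming rule that rose most within the genotype table, from 34.0 ± 10.4 to 12170 ± 8691 (n = 3 each; log2 change 8.14, SE 1.03, adjusted p 1.26e-04 in limma), with Cxcl5 (7.77), Tnip3 (7.64), Dmbt1 (7.52), Col10a1 (7.51), Areg (7.26) and Msln (7.02). Sbp was among the genes that fell most (log2 change -13.14, SE 1.36, adjusted p 4.21e-05 in limma), with Scgb2b7 (-11.25), Spink3 (-9.75) and Scgb2b20 (-9.72), and Scgb2b27, Sbpl and Scgb1b20 were listed at 0 in all 3 combined libraries. Of the 17 tested Wnt target genes 12 rose and 5 were not called (median 1.68, camera adjusted p 4.4e-05), with Apcdd1 (4.16), Prox1 (3.72) and Axin2 (2.49). Androgen-regulated and secretory luminal genes had 11 of 15 members lower and 2 higher (camera 0.0206), with Pbsn lower (log2 change -5.20, SE 0.92, adjusted p 9.65e-04 in limma) and Ndrg1 higher (2.01).

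All 23 cell cycle genes were higher in the combined group (median 3.36, camera 4.86e-13), including Ccna2 (3.86) and Kif11 (3.48), and 7 of 11 p53 and senescence genes rose and 1 fell (0.0137; Cdkn2a (6.73) and Cdkn2b (3.47)). Hypoxia and glycolysis genes rose for 10 of 12 members (camera 0.00172; Ankrd37 (3.63), Pkm (1.74) and Vegfa (1.65)). All 12 macrophage and monocyte markers (6.69e-05; Arg1 (4.13) and Cd68 (2.61)), all 6 neutrophil markers (0.00727; S100a8 (5.30) and Csf3r (3.75)) and all 12 cytokine and acute-phase genes (1.14e-05; Il1b (5.37) and Ccl20 (5.12)) rose, by camera. Interferon response genes rose for 13 of 15 (7.27e-05; Oas1a (3.03) and Ifi44 (3.17)) and squamous keratinisation markers for 7 of 10 (0.00953; Krt6a (6.66) and Krt16 (6.78)). All 10 smooth muscle markers fell (5.87e-05; Myh11 (-5.02) and Synpo2 (-4.20)), as did 8 of 9 skeletal muscle markers (0.0186; Tnnc2 (-7.85) and Acta1 (-7.29)) and 8 of 11 unfolded protein response genes (0.00727; Creld2 (-1.83) and Sdf2l1 (-1.50)). Fibroblast and matrix genes rose for 7 of 10 (Fn1 (2.70) and Col1a1 (3.52)), B and plasma cell markers for 4 of 7, T and NK cell markers for 4 of 7 (Cd4 (2.64) and Cd8a (2.36)) and endothelial markers for 4 of 10. Camera called none of these 4 lists (0.0509 for the first). Camera called the fibroblast, T and NK cell and endothelial lists without combined replicate 12, and the B and plasma cell list without combined replicate 11. Neuroendocrine markers were lower for 4 of 7 tested (Scg2 (-4.48) and Syp (-3.76)), FOXO target genes for 6 of 16 with 2 higher (Cited2 (-2.27) and Sesn3 (1.71)), and 0 of 8 seminal vesicle markers were called (median -3.81). Steroid synthesis and conversion genes had 2 of 4 higher and 1 lower, with a median of 0.43 but a mean of -0.98, Srd5a2 being lower (-5.81). Members changed when adjusted over the list alone numbered 13 of 17 for the Wnt target genes, 13 of 15 for the androgen-regulated and secretory luminal genes, 10 of 12 for the hypoxia and glycolysis genes and 9 of 11 for the unfolded protein response genes.

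Ctnnb1 and combined tumours shared 5571 calls in the same direction against wild type (2611 higher, 2960 lower), where independent lists of the same sizes would share 1019 and 1177. Unchanged groups simulated 20 times against the same wild-type libraries shared 0 calls, and the covariance of the fold changes was 2.04 against a simulated one of 0.0742. The 3 wild-type libraries are too few to split, so these comparisons share all their controls. Rescaling to equal totals moved the median of all genes by 0.48 and 0.50 in the Ctnnb1 and combined comparisons, and 78.7% and 82.1% of calls were then higher, against 48.5% and 47.9% as reported. Each list that camera called here has a median farther from 0 than that shift.

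**Figure D2:**
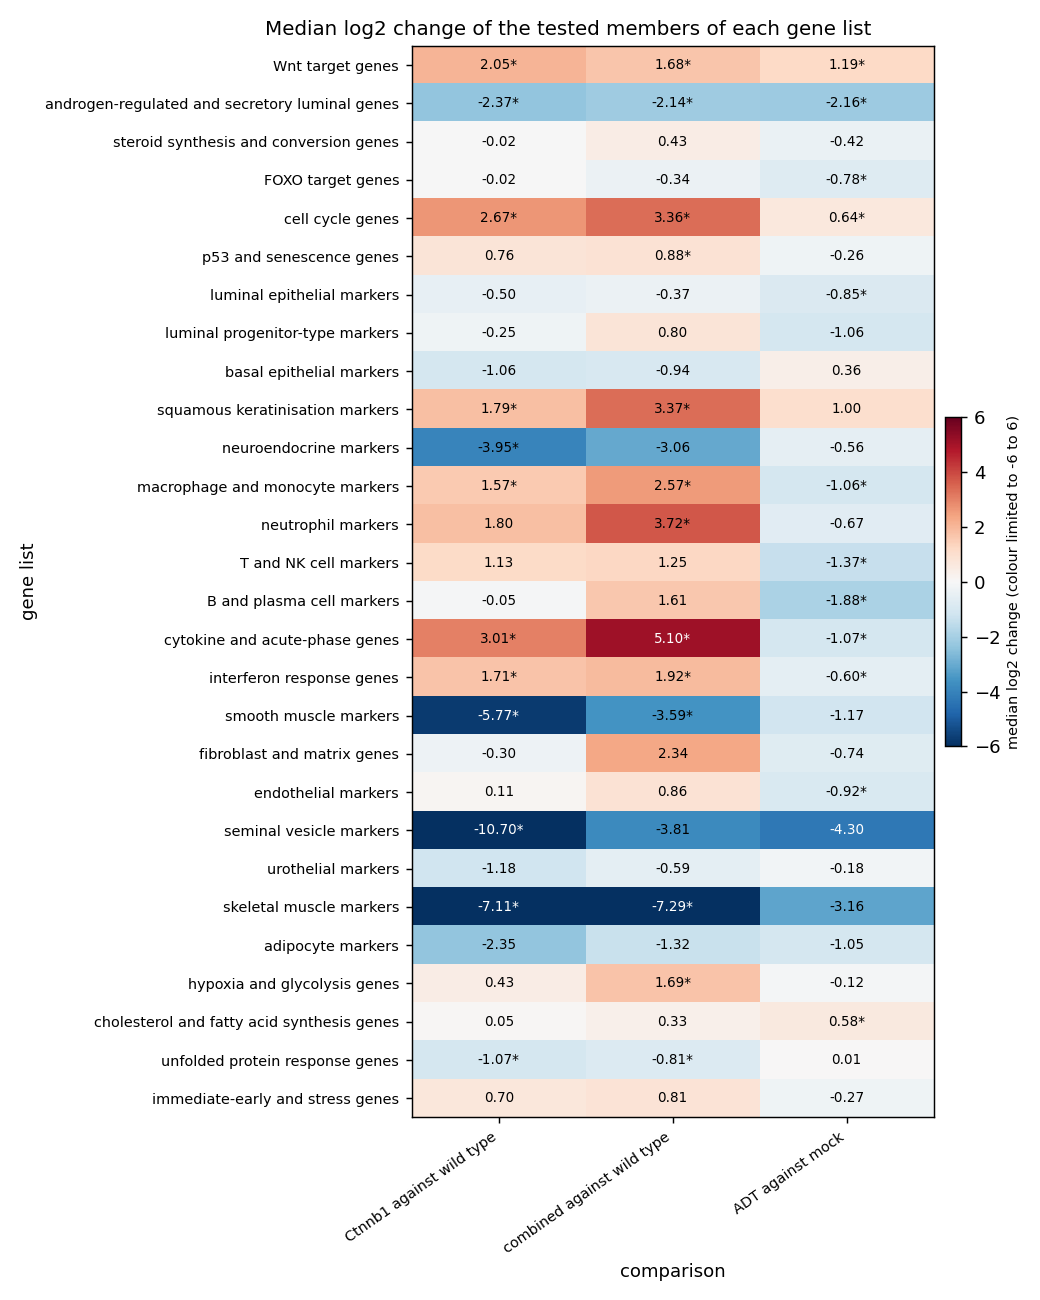
Median log2 change of the tested members of each gene list (vertical axis) in each of the 3 comparisons (horizontal axis), with an asterisk where camera with its preset correlation gave an adjusted p under the threshold. Wnt target genes have a median of 2.05 in Ctnnb1 and 1.68 in combined tumours against wild type, and cell cycle genes have positive medians in every column.

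The ADT comparison asks how tumours of the inducible model respond to androgen deprivation. With 3 ADT and 2 mock libraries limma called 2 of 23289 genes, both higher, whereas 3779 genes had an unadjusted p under 0.05. On simulated data for this comparison, the same test recovered 0 of 100 genes changed by 1 and 0 of 100 changed by 2 on the log2 scale, so the low count does not bound the number of changed genes. The genes called were Pycr1, which encodes an enzyme of proline synthesis (29290 ± 4533, n = 3, against 458 ± 10.6, n = 2; log2 change 5.98, SE 0.16, adjusted p 0.0135 in limma), and the tubulin gene Tubb4a (2575, 2440 and 2502 under ADT against 67 and 91; log2 change 4.99, SE 0.19, adjusted p 0.0313 in limma). Leaving out any of the 5 libraries left 0 calls in limma (2334 to 3979 genes at an unadjusted p under 0.05), with log2 changes of 5.87 to 6.09 for Pycr1 and 4.77 to 5.20 for Tubb4a. In these refits a mock library left alone was assumed to vary like the ADT group. The values of the groups did not overlap for 7724 genes, where chance gives 2 of the 10 ways to divide the 5 libraries. Ctnnb1 missed the threshold (log2 change 1.03, SE 0.18, adjusted p 0.133 in limma), although the groups did not overlap. The androgen-regulated gene Pbsn (0, 1 and 5 under ADT against 2533 and 2475) was not called either (adjusted p 0.0657 in limma), but was called under 6 of the other settings, with adjusted p from 7.82e-05 (all 17 libraries) to 0.0496 (robust prior variance). Ctnnb1 was called only with all 17 libraries (3.08e-04). Msmb was listed at 0 in all 3 ADT libraries and at 78 and 492 in the mock libraries.

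Although 0 members of any list were called over all genes, limma's camera called 13 of 29 lists, 3 as higher and 10 as lower. Fry called only the FOXO target genes (adjusted p 0.00488) and the androgen-regulated list (0.0122), so the other camera calls depend on the test. Its values were 0.164 for the Wnt target genes, 0.0887 each for the luminal epithelial and cholesterol lists and 0.612 for the cell cycle genes. Wnt target genes lay higher (median 1.19, camera adjusted p 2.63e-07), with log2 changes of Wif1 (4.23) and Lef1 (3.33). Cholesterol and fatty acid synthesis genes (0.58, 1.08e-05; Hmgcs1 (1.43)) and cell cycle genes (0.64, 4.59e-04; Mcm5 (0.90)) did too, the last not without ADT replicate 1. Androgen-regulated and secretory luminal genes lay lower (median -2.16, camera 4.81e-07; Pbsn (-10.10)), as did FOXO target genes (-0.78, 7.01e-04; Erbb3 (-1.59) and Pik3ip1 (-1.37)) and luminal epithelial markers (-0.85, 5.13e-05; Epcam (-1.78) and Cdh1 (-1.56)). The macrophage (-1.06, 0.00208; Csf1r (-1.45)), T and NK cell (-1.37, 0.0119) and endothelial lists (-0.92, 0.0119) were lower by camera but not without mock replicate 1, and the endothelial list not without ADT replicate 1. So were the interferon (-0.60, 0.0329) and red blood cell lists (-0.94, 0.0262), the first not without mock replicate 1 or ADT replicate 2 and the second not without either mock library or ADT replicate 1. Cytokine and acute-phase genes (-1.07, 0.0156) lost their call without mock replicate 2 or ADT replicate 1, and B and plasma cell markers (-1.88, 0.0119) without ADT replicate 2. Camera and fry did not call the seminal vesicle, skeletal muscle and fibroblast lists, although the log2 changes were below 0 for all 8 seminal vesicle markers (median -4.30, 0.0595), all 9 skeletal muscle markers (-3.16, 0.0818) and all 10 fibroblast and matrix genes (-0.74, 0.164), with 0 members called. Single libraries decided these lists. Camera called the seminal vesicle list as lower without ADT replicate 3 (5.65e-04) or mock replicate 1 (0.0146), the skeletal muscle list without ADT replicate 3 (2.47e-04), and the fibroblast list without mock replicate 2 (0.0015) or ADT replicate 1 (0.0044), but without mock replicate 1 the fibroblast list pointed up, uncalled (0.962). It also called the luminal progenitor-type list as lower without mock replicate 1 (0.00457) and the squamous list as higher without mock replicate 2 (6.93e-04), which pointed down, uncalled, without mock replicate 1 (0.11). The urothelial list differed in sign between median (-0.18) and mean (0.09), as did the unfolded protein response list (0.0091 and -0.01). When p was adjusted over the list alone, the members past the threshold were 11 of 15 for the androgen-regulated and secretory luminal genes, 8 of 19 for the Wnt target genes, 5 of 9 for the luminal epithelial markers, 4 of 15 for the cholesterol and fatty acid synthesis genes and 0 of 16 for the FOXO target genes.

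**Figure D3:**
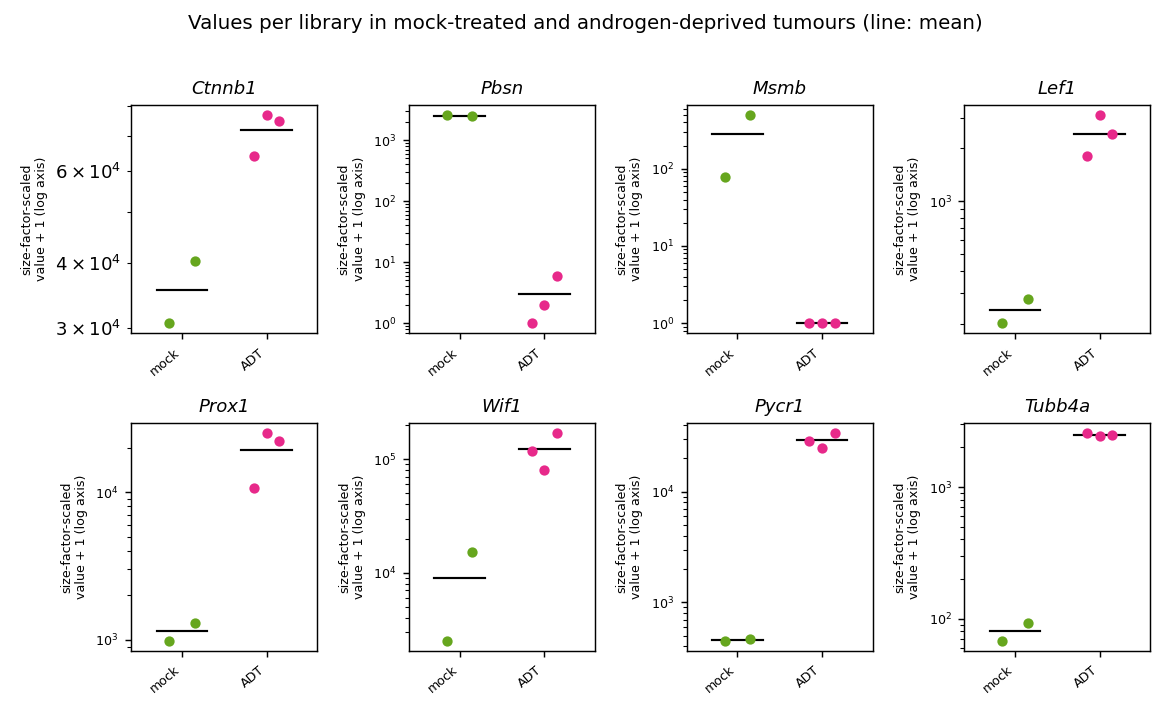
Size-factor-scaled value plus 1 (log axis) of 8 genes in each mock-treated (mock) and androgen-deprived (ADT) library; points are libraries and lines are means of 2 and 3. Pbsn lies at 2533 and 2475 with mock treatment and at 0, 1 and 5 under ADT, and the groups do not overlap for any gene drawn.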

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

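All tests of explanations in this part were chosen after the result was seen, and none gives more than a hypothesis.

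Genes listed only in the files of the wild-type and Ctnnb1 groups lie outside the genotype table. Of these 225 genes, 163 were higher in the Ctnnb1 group than in wild type and 1 was lower, and 144 were higher in the combined group and 0 lower. They drew attention because nearly all calls go the same way, but the direction is in part set by the filter of that file set, which lists genes by their values over 9 libraries, 6 of them tumours. In wild type 111 of the 225 had a mean under 15.6, the lowest mean over 9 libraries in that set, and 31 were at 0, so that these could be listed only through their tumour values. They supply 100 of the higher calls in each comparison. Among the other genes 63 were higher and 1 lower in the Ctnnb1 group, and 44 higher and 0 lower in the combined group. How much of that direction the filter sets was not tested. The hepatic and neuroendocrine factor gene Foxa2 was higher in both (log2 change 6.08 and 5.85), and Hsd17b3, of testosterone synthesis, was listed at 0 in all wild-type libraries and at 311, 244 and 235 in the Ctnnb1 libraries. Both belong to fixed lists whose counts in the report leave them out, Foxa2 to the neuroendocrine markers and Hsd17b3 to the steroid synthesis and conversion genes. Foxa2 rose where the 7 tested members of its list fell in the Ctnnb1 group. The filter in part sets the direction of the 225 genes, Foxa2 among them. It can also admit genes through wild-type values, as for Scg2, with a mean of 4.33 in the Ctnnb1 and 170 in the wild-type group. Foxa2 is therefore given as an exception to the fall of its list.

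Alb, the albumin gene, was at 26204, 212562 and 501486 under androgen deprivation and at 385 and 55 with mock treatment, and its log2 change of 9.90 missed the threshold (adjusted p 0.123). RNA from liver tissue is argued against, because the highest of 12 hepatocyte genes in any of the 3 libraries was 33 (Ahsg). Reads shared with the paralog Afp are argued against as well, as Afp reached at most 2.28% of Alb. An effect of androgen deprivation is left open. Every deprived library lies above both mock libraries, with Alb from 26204 to 501486. Its SE was 1.55, against 0.16 for Pycr1, which was called at a smaller log2 change of 5.98. The simulated data held no change above 2 on the log2 scale, so they do not tell how often a change of 9.90 is called. The missed threshold is counted neither way. Of the combined tumours, whose labels name no androgen deprivation, replicate 11 had Alb at 23163, beside 17 and 71 in replicates 10 and 12.

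Y-linked transcripts drew attention because they were low in ADT replicate 2, with log2 ratios to the median of the other libraries of -1.58 for Ddx3y, -1.66 for Uty, -1.39 for Kdm5d and -1.63 for Eif2s3y. RNA from female cells is argued against by Xist, at 72 in that library and at 638 in ADT replicate 1. Scaling of that library is argued against by the X-linked homologues, with a median log2 ratio of 0.06. The ratios lie within 0.27 of each other, as fewer transcripts from the whole Y chromosome would give. Ddx3y, however, was lower still in ADT replicate 3, at 348 against 968 in replicate 2, where Uty (1158), Kdm5d (1514) and Eif2s3y (3404) were not low. A Y-linked gene can therefore fall alone in these libraries, and the cause of the joint fall in replicate 2 is left open.

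Skeletal muscle markers were lower in Ctnnb1 and combined tumours than in wild type. Acta1 was at 38375, 14611 and 6487 in the wild-type libraries and at 2 to 2014 in the tumours. All 9 members have the same highest library (wild-type replicate 1) and the same lowest (wild-type replicate 3), with a median log2 range of 4.69 among the wild-type libraries against 0.22 for all genes, so striated muscle in the wild-type pieces fits and may be the source. A tumour library carries the same signal, since for 7 of 9 members 1 of 6 tumour libraries, Ctnnb1 replicate 15, lies at or above the lowest wild-type library (Myh4 at 3815 against 704, Ckm at 1374 against 885). Scaling of the wild-type libraries is argued against, because the largest fall of the median of all genes was -0.02. A part played by tumour genotype cannot be told apart, since 0 of 9 members had at least 2 tumour libraries at or above the lowest wild-type library but 7 of 9 had 1.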

How the results depend on the processing

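Median ratio, upper quartile and total rescaling, the robust prior variance, the fit of 9 libraries and the fit of 5 libraries with fewer genes were chosen after seeing the data. The DESeq2 Wald test, limma-voom, and the RLE and upper-quartile scalings of edgeR were not run, because the values are not counts. For every change below the cause was not tested unless stated.

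In the genotype comparisons every setting stayed within 1.5 times the count, and leaving out a library gave 6501 to 6938 (Ctnnb1 against wild type) and 6520 to 7475 genes (combined against wild type).

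The androgen deprivation count of 2 became 7 with a pseudocount of 5, 60 with the stricter filter, 54 and 48 with upper quartile and total rescaling, 29 with a robust prior variance, and 2352 with all 17 libraries. That fit changed both the libraries behind the estimate of the spread and the genes, of which it tested 13521 in place of 23289. The 5 libraries alone with only those genes (13515 of them with a value above 0) gave 12, so the smaller gene set by itself does not give the rise. It was 0 whenever a library was left out. With replicate number as a block (replicate block) it was also 0 in limma, with 3206 genes at an unadjusted p under 0.05. The labels name no pairing, only 2 numbers are shared, and deviations of libraries with the same number correlate at 0.272 and 0.133. That fit also sets aside ADT replicate 3, so the lost calls are no sign of a smaller change.

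Camera with an estimated correlation called 0 lists in each comparison, where 12, 13 and 13 were reported. Fry called 2 lists under androgen deprivation (FOXO target and androgen-regulated genes), and mixed fry called 22 and 24 lists against wild type. With a library left out camera called 11 to 13, 13 to 16 and 10 to 15 lists. Requiring a log2 change of at least 1 reduced the overlap to 2493 genes.

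Of 1817 values for named genes 1785 kept their direction and side of the threshold, 13 lost their call (12 of them Pycr1 and Tubb4a, and Ppp1r1b in Ctnnb1 tumours, at -0.54 under total rescaling with an adjusted p of 0.102) and 19, all under androgen deprivation, gained a call: Pbsn under 6 settings, Lef1 under 4, and Cdh1, Ctnnb1, Epcam, Erbb3, Hmgcs1, Mcm5, Msmb, Pik3ip1 and Wif1 only with all 17 libraries. For single lists 591 of 736 values stayed, 73 lost and 46 gained a call, and 26 moved.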

Other observations

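The splits were planned before the result was seen.

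Other divisions of the 6 libraries of each genotype comparison into groups of 3 were fitted in the same way. The real division gave 7784 genes for the Ctnnb1 and 7711 for the combined group, and the highest of the others gave 1 and 0 genes. Each other division mixes tumour and wild-type libraries, so the group difference enters the spread and lowers the calls. The other divisions therefore do not show what unchanged groups would give. At an unadjusted p under 0.05 the highest others gave 267 and 736 genes. In each comparison only 1 of 10 splits, the real one, reached the real count, and 10 splits are too few to reach a share under 0.05.

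The comparisons with wild type share their controls, and chance deviations of those libraries enter both. Simulated unchanged groups shared 0 calls with a covariance of 0.0742, against 2.04 in the data. Groups without changes leave few calls to share, so the 0 shared calls decide nothing. Independent sampling error of 3 simulated controls falls short of the covariance in the data. Genes were drawn independently, so deviations that many genes share were not simulated. A trait of the wild-type pieces, such as the striated muscle whose 9 markers rise and fall together, enters each comparison in the same way. The overlap is no measure of an effect shared by the genotypes.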
